A study of Mus musculus with 24 samples.

How the data were processed

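Liver RNA was sequenced from 24 mice in 8 groups of 3. The groups crossed genotype (wild type, WT, or a whole-body knockout of GCN2, KO), diet (a control diet, Control, or a diet without leucine, LeuD) and the circadian time of death (CT03 or CT15). GCN2, the product of Eif2ak4, is a protein kinase that responds to uncharged transfer RNA and phosphorylates the translation factor eIF2. Per the labels' protocols, mice kept on a 12-h light-dark cycle had 2 days on the control diet, the diet changed at the onset of the dark phase, constant darkness began 24 h later, and livers were taken after 8 days of darkness. Messenger RNA was enriched on oligo(dT) beads and libraries were made with a kit that, by its usual protocol, does not mark strand, so reads of overlapping or antisense genes cannot be told apart.

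The authors deposited 10 tables, each comparing a pair of groups. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 and DESeq, and the genome build was GRCm39. Their roles, the settings and the gene annotation are not given in the sources used here, and neither is the handling of reads that fit more than 1 gene. Values of near-identical genes, such as several H2 genes, the Mup genes and Eif3j1 with Eif3j2, are therefore uncertain. Per the file headers, each table holds a log2 fold change, a p-value, an adjusted p and values for 6 libraries. The library values deposited by the authors are a signal in the form of gene counts divided by a size factor per library, set separately in each table. Low values were whole multiples of 1 step per library, and 100% of values came out as whole reads within a tolerance of 0.01. Over 36 pairs of tables that share a library, 0 recovered reads differed. In 2 of the tables, a library had a size factor so near 1 that its step could not tell reads from rounding, and its reads were taken from its other tables. Each table listed 14674 to 15073 genes, and the lowest sum of reads over the 6 libraries of a table was 61. The tables together held 15741 genes, of which 14420 had a read count, which can be 0, for all 24 libraries. The depth was 34137121 to 44884200 reads per library. For genes with few reads, such as Npas2 in WT LeuD at CT15, counting error can be as large as the spread between mice. Over all genes mates of a group differed by a chi-square per degree of freedom of at least 34.7, so each library was counted once.

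The test planned before the data were examined was the quasi-likelihood test of edgeR for whole counts. For comparisons without library values it was the authors' deposited adjusted p. The files held neither form of data, so the values were tested on the log scale within each table by a test outside the plan. This was limma 3.58.1 with an intensity trend on log2(normalized count + 1), for 2 groups of 3 mice. It was a 2-sided moderated test with Benjamini-Hochberg adjustment over all genes of the table. A gene was called at an adjusted p under 0.05. Fold changes on this scale understate the change of genes with few reads. The 10 tables give the effect of time in 4 conditions, the effect of diet in 4 and the effect of genotype on the Control diet at 2 times. Differences between a pair of effects (time by diet, time by genotype, diet by genotype) came from 1 limma fit of the 12 libraries with the values of both tables, over genes with a mean normalized count of at least 10 in one of them. The comparison of KO with WT on the LeuD diet is in none of the tables. It was added after the data were examined, from the recovered reads put on 1 scale over the 24 libraries. The genes named in it were also chosen then, outside the rule below. Group means are given as normalized counts ± SD with n = 3 mice per group, and fold changes as log2 ± SE. Levels set across tables used the recovered reads over size factors of all 24 libraries.

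Genes were named by a rule written before the data were examined: Eif2ak4; the 6 genes with the largest positive and the 6 with the largest negative change among called genes with a mean of at least 50 and an established symbol; up to 4 members with the lowest p from each of 34 gene lists; and a fixed set of clock and stress genes. The lists covered metabolic pathways, stress responses, sex-biased liver genes and markers of other cell types. They were tested with the camera test of limma on signed z values with a correlation preset at 0.01, adjusted over 533 tests of a list in a comparison. Of these, 210 passed an adjusted p of 0.05 and 0 did so with an estimated correlation (137 passed with a preset of 0.05), where the lowest adjusted p was 0.479. Libraries with exchanged labels gave up to 225 passing tests, so a camera p below is a description of how list members moved together, and each list is reported first by its called members.

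The gene calls of the 16 planned comparisons, and the list test for time in WT Control, were tested on simulated counts drawn from the real means and library sizes with known changes. The comparison of genotypes on LeuD, the test of gene neighbours and the diet axes had no simulation. In the tables of WT libraries 56% to 65% of 2-fold changes and 84% to 92% of 4-fold changes were recovered, as the simulation of time in WT Control recovered 65% and 88%. In the tables of KO libraries alone the shares were 9% to 19% and 74% to 82%, and for genotype on the Control diet they were 37% and 89% at CT03 and 9% and 69% at CT15. For the differences between a pair of effects they were 4% to 32% and 58% to 85%. Each simulation changed 100 genes 2-fold and 100 genes 4-fold, and 2 to 20 unchanged genes were called. Diet in WT at CT03 had 20, beside 59 and 92 changed genes, and diet in KO at CT15 had 12, beside 13 and 82. Time by genotype on Control had 2, beside 15 and 69. For both diet effects false calls were a larger share than the adjusted p threshold aims for. The adjusted p depends on how many genes change, so recovery and false calls can differ in the real tables. The within-group SD (median over genes, log2 scale) was 0.162 to 0.186 in the WT groups and 0.212 to 0.268 in the KO groups. Alternatives planned in advance were other thresholds and filters, another centring, the replicate number as a block and the removal of each library in turn. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads, the same test on all 24 libraries, the authors' deposited adjusted p, pseudocounts of 0.5 and 5 and the removal of libraries with pancreas transcripts were added after the data were examined. Of these, edgeR on the recovered reads and the deposited adjusted p are the tests of the plan, used here as alternatives. The fit of all 24 libraries pools the spread of a gene over WT and KO groups. As the KO groups had the larger spread, it can understate the error of KO comparisons and overstate that of WT comparisons. The reference annotation used here (GRCm38) differs from the build of the authors, so it served for the order of genes along a chromosome alone and no positions are printed. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.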

Results

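Gene expression was measured by sequencing of polyadenylated RNA from the livers of 24 mice. WT mice and mice with a whole-body knockout of GCN2 (KO) ate the Control or the LeuD diet and were killed at CT03 or CT15, which gave 8 groups of 3 mice. Libraries held 34137121 to 44884200 reads in listed genes. Values are normalized counts of a table (mean ± SD, n = 3 mice per group), changes are on the log2(normalized count + 1) scale with their SE, and adjusted p values are from limma with Benjamini-Hochberg adjustment. With 3 mice per group these p values measure the spread between mice of this study alone. Pancreas acinar transcripts took 3782 to 13365.4 RPM (reads scaled to library size) in 3 LeuD libraries (KO CT03 replicate 1 at 13365.4, KO CT15 replicate 3 at 7069.2, WT CT15 replicate 1 at 3782). They took 573.2 in KO Control CT15 replicate 1, 226.4 in KO Control CT03 replicate 3 and 9.2 to 65.2 in the others. Mitochondrially encoded genes took 2.24% to 4.14% of reads in the KO LeuD libraries and 4.23% to 6.31% in all others, and albumin 11.81% to 15.34% against 6.14% to 10.91%.

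**Figure D1:**
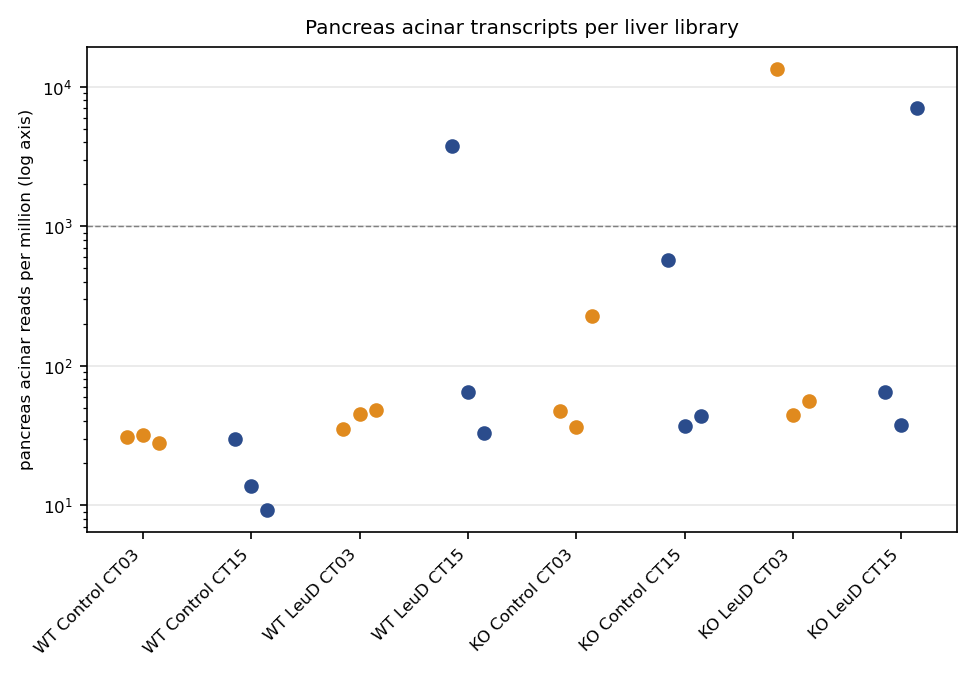
RPM in pancreas acinar genes for each of the 24 libraries, on a log axis, by group. The 3 highest libraries hold 3782 to 13365.4 RPM and all were labelled LeuD, while the other 9 LeuD libraries stay at or below 65.2.

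Eif2ak4, the gene that encodes GCN2, was not called for genotype in any comparison. On 1 scale over the 24 libraries it had 325 ± 16.5 normalized counts in the 12 WT mice (287 to 349) and 364 ± 71.4 in the 12 KO mice (243 to 462). In the genotype tables Eif2ak4 differed by 0.39 ± 0.13 at CT03 (adjusted p = 0.57) and by 0.34 ± 0.17 at CT15 (adjusted p = 0.791). On LeuD, on the scale over the 24 libraries, it differed by -0.10 ± 0.17 at CT03 (323 ± 9.65 in WT, 305 ± 53.5 in KO, adjusted p = 0.814) and by -0.08 ± 0.14 at CT15 (331 ± 15.9 and 313 ± 17.6, adjusted p = 0.805). Reads summed over the whole gene say nothing about the loss of an exon, so this does not check the label. Eif3j2, which encodes a subunit of translation initiation factor eIF3, separated the genotypes with no overlap, at 534 to 883 normalized counts in KO and 49.4 to 101 in WT, so 0 libraries stood on the wrong side. Its near-identical paralog Eif3j1 went the other way, at 1358 to 2051 in KO and 2116 to 2893 in WT. Whether reads moved between the paralogs was not tested.

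The first question was how the liver transcriptome differed between CT03 and CT15 in WT mice on the Control diet. Clock genes were among the called genes. Per2, a repressor of the clock, rose from 455 ± 76.9 at CT03 to 2534 ± 843 at CT15 (2.44 ± 0.23, adjusted p = 0.00718). The ubiquitin protease gene Usp2, a clock output, rose from 107 ± 42.9 to 1246 ± 438 (3.54 ± 0.34, adjusted p = 0.00718). Nr1d1, the repressor REV-ERBα, fell from 2166 ± 527 to 379 ± 117 (-2.53 ± 0.25, adjusted p = 0.00718). Of the lipid genes Thrsp, a regulator of lipogenesis, rose by 3.47 ± 0.43 (8228 ± 5630 to 80860 ± 24300) and Elovl6, a fatty acid elongase, by 2.73 ± 0.39. Acly, which makes cytosolic acetyl-CoA, rose by 2.00 ± 0.26. The heat shock chaperone gene Hspa1b rose from 348 ± 67.7 to 1713 ± 112 (2.31 ± 0.15, adjusted p = 0.00643). The endoplasmic reticulum (ER) folding factors Sdf2l1 and Manf fell by 1.32 ± 0.21 and 0.86 ± 0.14.

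By list, 8 of 21 measured clock genes were called higher at CT15 and 1 lower, with 9 higher and 3 lower when adjusted over the list alone. Among fatty acid synthesis genes 4 of 19 were called higher, 19 had a positive change, and 8 passed when adjusted over the list alone (camera adjusted p = 1.51e-09, adjusted p = 0.767 with an estimated correlation). Heat shock genes had 4 of 14 called higher (Hspa1b, Hspa1a, Hsph1 and Dnajb1) and 12 higher with 1 lower when adjusted over the list alone. ER chaperones had 2 of 18 called lower, 13 when adjusted over the list alone. In total 212 genes were called, 130 higher and 82 lower at CT15, of 14967. Of the fixed clock genes, Arntl (-0.43 ± 0.22, adjusted p = 0.369), Npas2 (-3.26 ± 0.75, adjusted p = 0.0854) and Dbp (0.83 ± 0.66, adjusted p = 0.562) did not pass. The count depended on each library: it was 133, 4 and 59 without CT03 replicates 1, 2 and 3 and 52, 62 and 56 without CT15 replicates 1, 2 and 3. Among the 35 named genes that were called Hspa1b alone passed without each library in turn. The authors' deposited table held 907 genes at an adjusted p under 0.05, and all 212 were among them.

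In WT mice on the LeuD diet clock genes changed with time too. Dbp, a clock-driven transcription factor, rose from 42.8 ± 7.1 to 1614 ± 571 (5.15 ± 0.27, adjusted p = 4.57e-05). Per3 rose by 4.85 ± 0.22 and Per2 by 3.42 ± 0.12 (225 ± 18.9 to 2419 ± 271, adjusted p = 9.78e-06). Npas2, an activator of the clock, fell from 698 ± 136 to 6.53 ± 2.53 (-6.57 ± 0.28, adjusted p = 1.8e-05) and its relative Arntl, which encodes BMAL1, by 2.66 ± 0.36. Among the drug metabolism genes that rose were Por, the electron donor of cytochromes P450 (2.60 ± 0.12), Cyp2a5 (2.68 ± 0.18) and Alas1, the first enzyme of haem synthesis (3.13 ± 0.29). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 1663 ± 827 to 12060 ± 3040 (2.98 ± 0.38, adjusted p = 0.00291). Its repressor Nr0b2 and the bile salt exporter Abcb11 fell by 1.12 ± 0.1 and 1.51 ± 0.19. Igfbp1, an insulin-repressed binding protein, fell from 13540 ± 3450 to 2187 ± 837 (-2.66 ± 0.27, adjusted p = 0.00115). Irs2 and Pdk4 fell by 1.87 ± 0.23 and 1.39 ± 0.28.

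The clock list had 12 of 21 genes called higher and 5 lower (12 and 6 when adjusted over the list alone), drug metabolism 6 of 15 higher (8 when adjusted over the list alone). ER chaperones had 7 of 18 lower (11 when adjusted over the list alone), including Syvn1, Pdia4, Hyou1 and Manf. Fatty acid synthesis had 4 of 19 higher and 1 lower (13 and 2 when adjusted over the list alone), the latter being Mlxipl, a glucose-responsive activator of that pathway. Amino acid catabolism had 8 of 26 higher and 2 lower. Of female-biased liver genes 3 of 9 were called higher (Fmo2, Cyp2a4 and Acot3), and of male-biased genes 2 of 14 lower. Among the stress genes Atf5, a transcription factor of the integrated stress response, fell from 62130 ± 11200 to 23780 ± 5830 (-1.40 ± 0.2, adjusted p = 0.00519). Trib3 (-1.24 ± 0.4, adjusted p = 0.0924), Asns (0.67 ± 0.22, adjusted p = 0.0916) and Fgf21 (1.69 ± 0.53, adjusted p = 0.0828) did not pass. In total 1424 genes were called, 640 higher and 784 lower at CT15, of 14825. Counts fell to 931, 561 and 838 without CT03 replicates 1, 2 and 3 and to 894 without CT15 replicate 2. Of the 78 named genes that were called, 48 passed without each library in turn. Without CT15 replicate 1, the library with acinar transcripts, 970 genes were called. EdgeR on all 24 libraries called 701 and the authors' deposited table held 2028, of which 1418 are among the 1424.

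**Figure D2:**
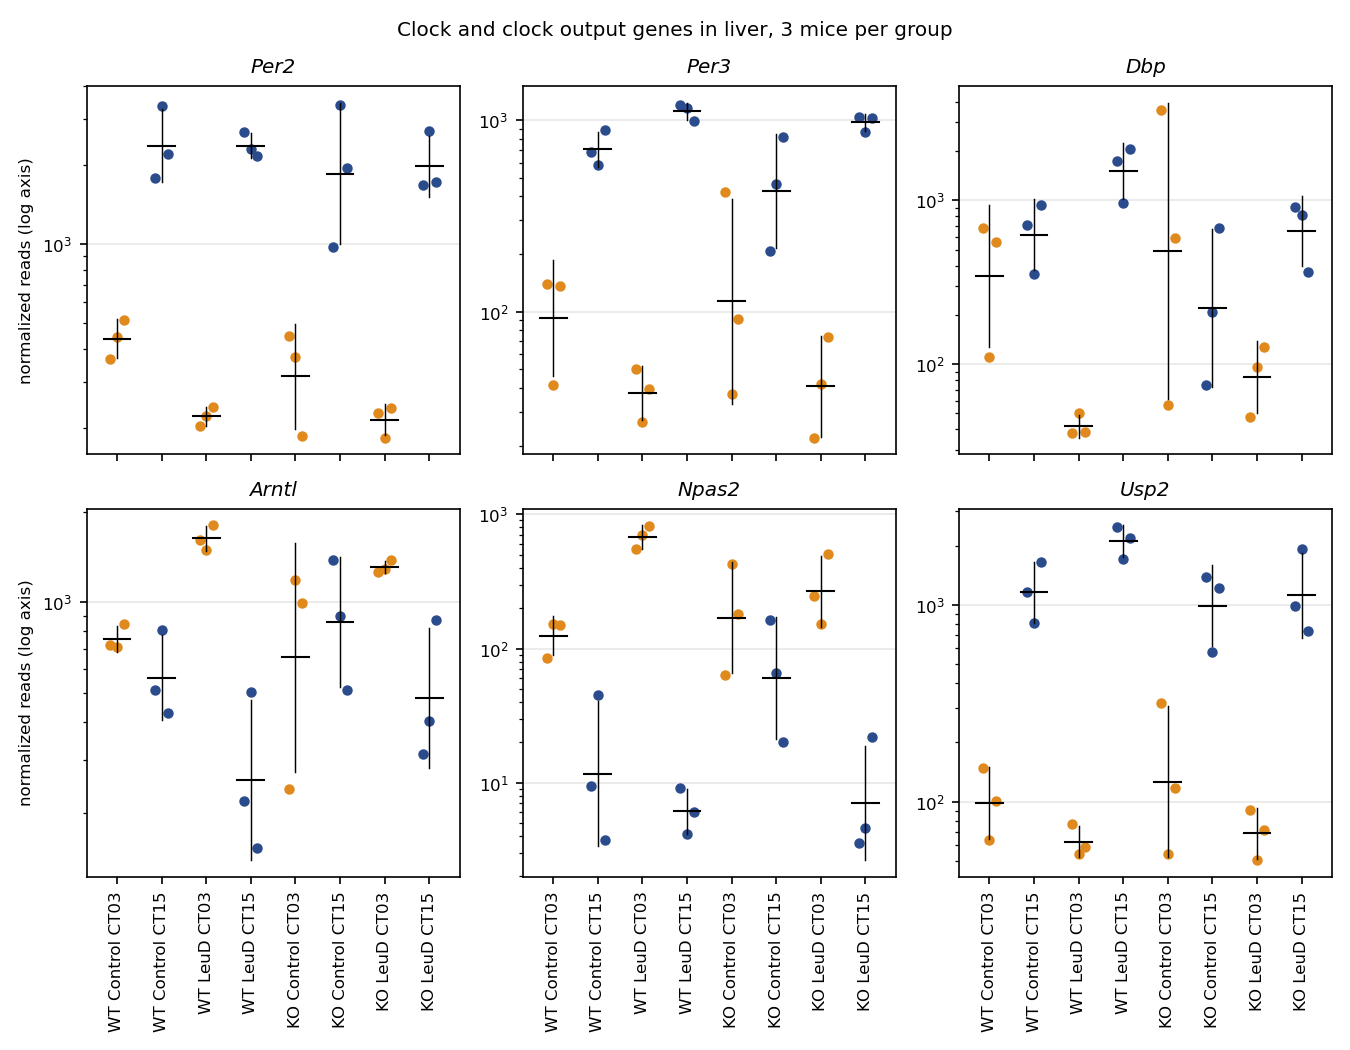
Normalized counts of 6 clock genes (Per2, Per3, Dbp, Arntl, Npas2 and Usp2) in each library, on a log axis and on 1 scale over 24 libraries, by genotype and diet (points: CT03 orange, CT15 blue; bar: geometric mean; line: 1 SD on the log scale). In WT LeuD livers Npas2 lies between 556 and 826 normalized counts at CT03 and between 4.21 and 9.22 at CT15 in that comparison's table.

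The pair of WT comparisons share no library. Of the 211 genes called on the Control diet and measured in both, 205 (97.2%) had the same sign on the LeuD diet, against 71.1% of all genes, and the slope of the LeuD on the Control change was 0.94. Both comparisons called 92 genes higher and 54 lower, against 5.68 and 4.34 for independent lists. The test of the difference of time effects between diets called 1 gene of WT livers, Nfil3, a clock repressor with a time effect of 0.00 ± 0.13 on Control and -1.49 ± 0.12 on LeuD (difference -1.49 ± 0.18, adjusted p = 0.0382), and 958 genes had an unadjusted p under 0.05. The count was 6 without WT Control CT03 replicate 2, 7 without WT LeuD CT15 replicate 2 and 0 without any other of the 12 libraries, the acinar library (WT LeuD CT15 replicate 1) included. Of the 21 clock genes Nfil3 was the single one called in this test. The others, such as Dbp (4.31 ± 0.8, adjusted p = 0.251) and Npas2 (-3.31 ± 0.88, adjusted p = 0.442), are not shown to differ in their time effect between diets.

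In KO mice on the Control diet few genes were called for time. Tsku, a secreted liver protein, rose from 313 ± 124 to 2670 ± 316 (3.15 ± 0.27, adjusted p = 0.0182), the chaperone gene Hsph1 from 959 ± 152 to 4514 ± 89.3 (2.25 ± 0.15, adjusted p = 0.0157). The glucocorticoid-induced Tsc22d3 and the centriole gene Tedc2 rose by 1.68 ± 0.14 and 1.64 ± 0.13. H2-Eb1, a major histocompatibility complex (MHC) class II chain, fell from 538 ± 180 to 40.6 ± 8.82 (-3.67 ± 0.28, adjusted p = 0.0159) and the class I gene H2-T23 by 3.07 ± 0.29. The clock genes had large changes with a large spread and did not pass: Nr1d1 -4.09 ± 0.71 (adjusted p = 0.127), Per2 2.55 ± 0.49 and Cry1 2.19 ± 0.42 (both adjusted p = 0.159). Dbp ranged from 54.8 to 3473 normalized counts among the 3 CT03 mice. Heat shock genes had 1 of 14 called and 10 higher with 1 lower when adjusted over the list alone (camera adjusted p = 1.32e-10, adjusted p = 0.479 with an estimated correlation). The 6 genes (4 higher, 2 lower, of 14745) became 0, 2 and 0 without CT03 replicates 1, 2 and 3, 0 without CT15 replicate 2 or 3, and 76 without the 2 libraries above 200 RPM in acinar genes. At an unadjusted p under 0.05 there were 1819 genes, edgeR on all 24 libraries called 553, and the authors' deposited table held 357.

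In KO mice on the LeuD diet clock and lipid genes changed with time. Per2 rose from 215 ± 28.4 to 2010 ± 578 (3.19 ± 0.22, adjusted p = 0.00164), Per3 by 4.53 ± 0.39, Bhlhe40 by 2.71 ± 0.18 and Dbp by 2.93 ± 0.44, and Npas2 fell by 5.01 ± 0.67 (adjusted p = 0.0206). Thrsp rose by 4.74 ± 0.5 and Acacb, a mitochondrial acetyl-CoA carboxylase, by 2.58 ± 0.26. Female-biased genes had 3 of 12 members called higher, with Fmo2 (3.04 ± 0.3) and the oestrogen sulfotransferase gene Sult1e1 (4.10 ± 0.57) among them. Ccne2 and Rrm2, genes of the entry into DNA replication, rose by 2.43 ± 0.24 and 2.62 ± 0.35. Of the clock list 7 of 21 were called higher and 1 lower (11 and 4 when adjusted over the list alone), and of fatty acid synthesis 2 of 19 higher (12 when adjusted over the list alone; camera adjusted p = 1.3e-10, adjusted p = 0.767 with an estimated correlation). The lymphocyte markers had 0 of 11 called, 11 negative and 6 lower when adjusted over the list alone. The H2 genes H2-Eb1, H2-T23 and H2-T22 were called lower at CT15, by -3.63 ± 0.34, -2.39 ± 0.21 and -2.29 ± 0.2. In total 120 of 14914 genes were called, 96 higher and 24 lower. The count was 60, 31 and 605 without CT03 replicates 1, 2 and 3 and 45, 51 and 33 without CT15 replicates 1, 2 and 3, and 9 without both acinar libraries (CT03 replicate 1 and CT15 replicate 3). Of the 26 named genes that were called, 12 passed without each library in turn. EdgeR on all 24 libraries called 1185 genes and the authors' deposited table held 844, among them these 120.

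Across genotypes the time effects mostly had the same sign. The slopes given here are over genes picked by their calls in WT, which alone can bring a slope below 1. They thus do not show weaker time effects in KO. Of 211 genes called in WT Control, 202 (95.7%) had the same sign in KO Control, against 66% of all genes, with a slope of 0.71. Of 1416 called in WT LeuD, 1264 (89.3%) had the same sign in KO LeuD, against 64.6%, with a slope of 0.67, and both comparisons called 73 genes higher and 16 lower, against 4.2 and 1.3 for independent lists. The difference of time effects between genotypes called 4 genes on Control (H2-Eb1, H2-T22, H2-Q5 and H2-T23, all lower in KO at CT15) and 3 on LeuD (H2-T22, H2-Eb1 and H2-T23), and no clock gene. In the simulations this test recovered 15% of 2-fold changes on Control and 10% on LeuD. Genes not called are thus not shown to have equal time effects. On Control the 4 calls became 0 without KO Control CT03 replicate 1, WT Control CT03 replicate 2 or 3, or WT Control CT15 replicate 2 or 3. They became 1 without WT Control CT03 replicate 1 or any KO Control CT15 library, and 2 without KO Control CT03 replicate 2 or WT Control CT15 replicate 1. On LeuD the same 3 genes passed without each library in turn, the count was 36 without KO LeuD CT03 replicate 3 and 6 without KO LeuD CT15 replicate 2, and it was 0 without the 3 acinar libraries. The H2 genes split the KO mice by time in both diets: H2-Eb1 had 33.4 to 51.8 and 33.2 to 69.2 normalized counts in the KO Control and KO LeuD mice at CT15, but 434 to 768 and 451 to 831 in those at CT03. The difference of time effects between diets in KO mice called 0 genes with limma (edgeR on the recovered reads 0, edgeR on all 24 libraries 25), with 930 at an unadjusted p under 0.05 and 1 called without KO LeuD CT03 replicate 3.

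The next question was what the LeuD diet changed at each time. In WT livers at CT03 5 of 32 measured genes of the integrated stress response (ISR) list rose. Igfbp1 went from 1090 ± 178 on Control to 13290 ± 3370 on LeuD (3.59 ± 0.2, adjusted p = 0.000506). Cdkn1a, the cell cycle inhibitor p21, rose by 2.37 ± 0.16, and Irs2, Angptl4 and Cyp4a14 by 2.51 ± 0.24, 2.02 ± 0.16 and 1.76 ± 0.15. Of the ISR genes, Psat1, an enzyme of serine synthesis, rose from 34.2 ± 9.53 to 221 ± 79.4 (2.62 ± 0.33, adjusted p = 0.00959). Atf5 rose from 22420 ± 3730 to 61010 ± 10900 (1.44 ± 0.18, adjusted p = 0.00959), Trib3 by 2.29 ± 0.4 and Mthfd2 by 1.17 ± 0.22. Scd1, the stearoyl-CoA desaturase of lipogenesis, fell from 368400 ± 204000 to 31030 ± 16500 (-3.54 ± 0.48, adjusted p = 0.0124). Mfsd2a, Serpina4-ps1 and Gstp1 fell by 3.69 ± 0.48, 4.51 ± 0.5 and 1.92 ± 0.18. Clock genes moved both ways: Npas2 and Arntl rose by 2.43 ± 0.24 and 1.10 ± 0.11, and Dbp and Per2 fell by 3.02 ± 0.59 and 0.98 ± 0.15.

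The ATF4 and ISR list had 5 of 32 genes called higher, 26 positive and 13 higher when adjusted over the list alone (camera adjusted p = 4.82e-06, adjusted p = 0.606 with an estimated correlation). Asns (1.2 ± 0.39, adjusted p = 0.16), Chac1 (1.43 ± 0.33, adjusted p = 0.067), Ddit3 (0.58 ± 0.15, adjusted p = 0.098) and Fgf21 (0.22 ± 0.52, adjusted p = 0.868) did not pass. Cytosolic ribosomal protein genes had 4 of 86 called higher (Rpl13a, Rpl23, Rpl5 and Rpl3, by 0.56 to 0.58), 83 positive and 67 when adjusted over the list alone (5.1e-28, and adjusted p = 0.767 with an estimated correlation). Fatty acid synthesis had 3 of 19 lower (9 when adjusted over the list alone), male-biased genes 5 of 14 lower, NRF2 and glutathione genes 3 of 14 lower, and the clock list 4 of 21 higher and 5 lower (5 and 8 when adjusted over the list alone). The erythroid marker Alas2 fell by 1.24 ± 0.19, and 6 of 6 erythroid markers were lower when adjusted over the list alone. Haemoglobin took 78.2 to 275.5 RPM in LeuD and 212.2 to 461.7 in Control libraries. In total 330 of 14729 genes were called, 193 higher and 137 lower. Counts were 86 and 80 without Control replicates 2 and 3 and 75 and 82 without LeuD replicates 2 and 3. Of the 49 named genes that were called, 13, with Psat1, Atf5, Igfbp1, Arntl and Npas2 among them, passed without each library in turn. EdgeR on all 24 libraries called 28 genes, and the authors' deposited table held 960, of which 328 are among the 330.

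**Figure D3:**
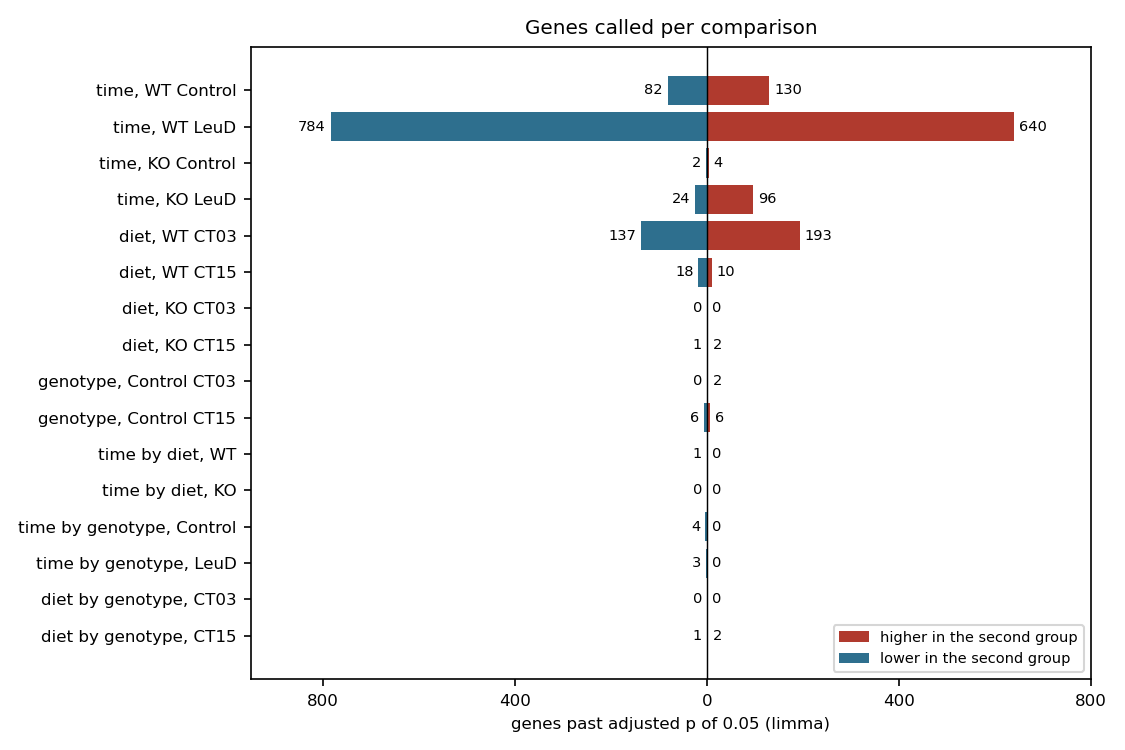
Genes called by limma at an adjusted p of 0.05 in each of the 10 deposited comparisons and in the differences between a pair of effects (bars from 0, with higher and lower in the second group shown apart). In the deposited comparisons counts run from 0 (diet in KO at CT03) to 1424 (time in WT LeuD), and those of KO livers alone hold at most 120. The differences hold at most 4.

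At CT15 the LeuD diet raised Asns, the asparagine synthetase, in WT livers from 169 ± 30.5 to 708 ± 165 (2.05 ± 0.2, adjusted p = 0.0245). It raised the hormone gene Fgf21 from 59.4 ± 24.1 to 479 ± 158 (3.02 ± 0.37, adjusted p = 0.0336) and Psat1 from 49.1 ± 13.2 to 247 ± 53.4 (2.32 ± 0.25, adjusted p = 0.0262). The metallothionein gene Mt2 rose by 3.87 ± 0.36 and the acute phase gene Apcs by 2.16 ± 0.23. Scd1 fell from 894700 ± 249000 to 90290 ± 62700 (-3.48 ± 0.45, adjusted p = 0.0376). Elovl5 fell by 1.74 ± 0.18, the water channel gene Aqp8 by 3.53 ± 0.42 and Chrna4 by 5.21 ± 0.55. Per1 rose by 1.25 ± 0.1 (adjusted p = 0.0146), while Per2 did not differ (0.00 ± 0.22, adjusted p = 0.997) and Trib3 (1.88 ± 0.34, adjusted p = 0.0972) and Atf5 (1.15 ± 0.24, adjusted p = 0.136) did not pass. The ATF4 and ISR list had 3 of 32 called higher and 13 when adjusted over the list alone (camera adjusted p = 2.1e-11, adjusted p = 0.606 with an estimated correlation). Fatty acid synthesis had 2 of 19 called lower, 18 negative and 15 lower when adjusted over the list alone (3.23e-14, and adjusted p = 0.767 with an estimated correlation). Acute phase genes had 2 of 24 called higher, and 83 of 87 ribosomal protein genes were positive with 0 called and 61 when adjusted over the list alone. All 12 of the pancreas acinar markers were positive, with 0 called and 10 when adjusted over the list alone, and LeuD replicate 1 is the library with acinar transcripts.

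In this comparison 28 of 15073 genes were called, 10 higher and 18 lower. The count was 0, 14 and 132 without Control replicates 1, 2 and 3 and 12, 0 and 9 without LeuD replicates 1, 2 and 3. EdgeR on the recovered reads called 14, edgeR on all 24 libraries 3, and the authors' deposited table held 523. The diet effects of WT livers at both times share no library. Of the 330 genes called at CT03, 274 (83%) had the same sign at CT15, against 64.1% of all genes, with a slope of 0.55, and both called 5 genes higher (0.12 for independent lists) and 10 lower (0.17). As the genes were picked by their calls at CT03, a slope below 1 can arise from that choice alone.

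In KO livers at CT03 limma called 0 genes for diet. At an unadjusted p under 0.05 there were 2173, edgeR on the recovered reads called 0, edgeR on all 24 libraries 643, and the authors' deposited table held 520. Gdf15 and Ddit3, both ISR genes, had changes of 3.18 ± 0.53 (146 ± 78.5 to 1321 ± 786, adjusted p = 0.189) and 1.84 ± 0.36 (adjusted p = 0.205), and Asns of 1.97 ± 0.77 (418 ± 176 to 2150 ± 1520, adjusted p = 0.315). The ATF4 and ISR list had 30 of 33 positive and 2 higher when adjusted over the list alone (camera adjusted p = 3.74e-06, adjusted p = 0.767 with an estimated correlation). Branched-chain amino acid catabolism had 19 of 19 negative and 12 lower when adjusted over the list alone (1.9e-10, and adjusted p = 0.767 with an estimated correlation), and ribosomal proteins 84 of 86 positive and 77 higher when adjusted over the list alone. Without LeuD replicate 3 the comparison called 1234 genes and without Control replicate 3 it called 5. In that LeuD library Psat1 stood at 23.9 normalized counts against up to 832 in its mates, and Asns at 404 against up to 3200.

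**Figure D4:**
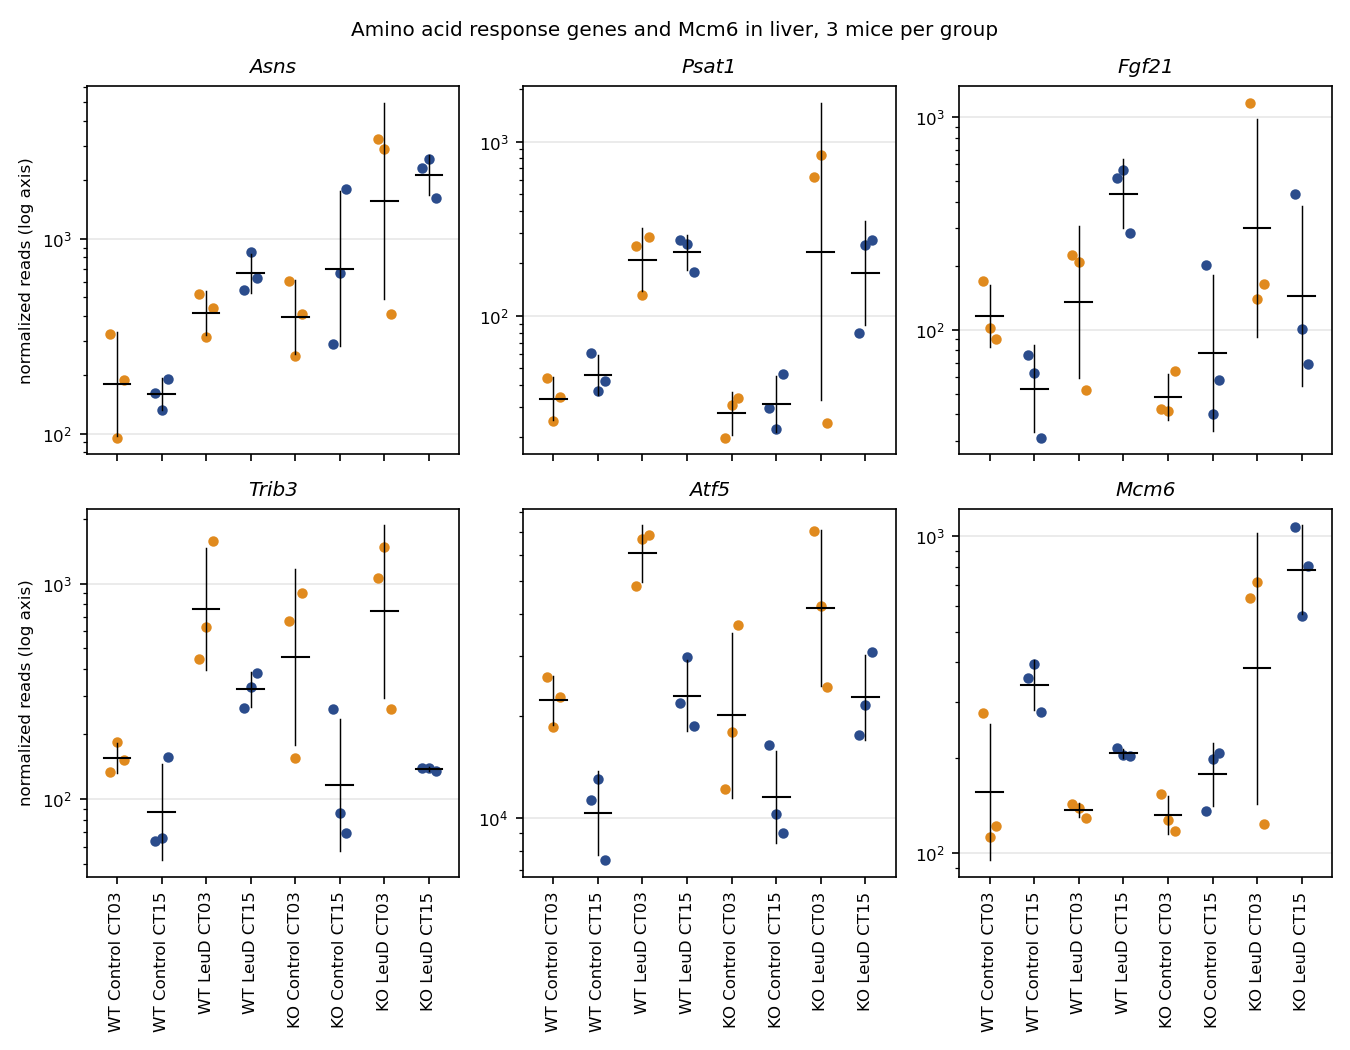
Normalized counts of the stress and cell cycle genes Asns, Psat1, Fgf21, Trib3, Atf5 and Mcm6 in each library, on a log axis and on 1 scale over 24 libraries, by genotype and diet (points: CT03 orange, CT15 blue; bar: geometric mean; line: 1 SD on the log scale). On the LeuD diet at CT15 Asns averaged 675 ± 158 in WT and 2160 ± 484 in KO livers, and Mcm6 averaged 207 ± 6.54 and 810 ± 253. On the Control diet at CT15 Asns averaged 161 ± 29.5 in WT and 916 ± 783 in KO livers, and Mcm6 averaged 343 ± 59.5 and 180 ± 38.6.

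In KO livers at CT15 the LeuD diet raised Id1, an inhibitor of basic helix-loop-helix factors, from 300 ± 63 to 1362 ± 137 (2.20 ± 0.2, adjusted p = 0.0271). It lowered Ddah1, which degrades methylated arginines, from 3697 ± 248 to 964 ± 158 (-1.95 ± 0.16, adjusted p = 0.0264). AI506816, outside the naming rule and chosen after its values were seen, was the other called gene and was higher. Psat1 had a change of 2.45 ± 0.51 (adjusted p = 0.0995) and Asns of 1.59 ± 0.58 (adjusted p = 0.253). Cell cycle genes had 15 of 16 positive and 8 higher when adjusted over the list alone (camera adjusted p = 5.21e-06, adjusted p = 0.767 with an estimated correlation), and mitochondrially encoded genes 30 of 31 negative and 12 lower when adjusted over the list alone (1.05e-10, and adjusted p = 0.767 with an estimated correlation). The 3 calls of 14834 genes became 0 without each library except Control replicate 1, without which 203 genes were called. The authors' deposited table held 698 genes, edgeR on all 24 libraries called 1213, 2376 genes had an unadjusted p under 0.05, and 0 were called without LeuD replicate 3, the library with acinar transcripts. Since the fit of all 24 libraries pools the spread of KO with that of the less variable WT groups, its count for KO livers can be too high.

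The question of whether GCN2 changes the response to the diet was addressed by the difference of diet effects between genotypes. At CT15 Mcm6, a subunit of the replicative helicase, had a diet effect of -0.72 ± 0.16 in WT and 2.13 ± 0.28 in KO (difference 2.85 ± 0.34, adjusted p = 0.0341), Slfn9 of -0.44 ± 0.21 and 2.84 ± 0.36 (3.28 ± 0.45, adjusted p = 0.0475) and Ugt3a2, a glycosyltransferase, of 0.04 ± 0.11 and -1.18 ± 0.15 (-1.22 ± 0.17, adjusted p = 0.0475). Cell cycle genes had 1 of 16 called, 16 positive and 8 when adjusted over the list alone (camera adjusted p = 3.59e-11, adjusted p = 0.479 with an estimated correlation). The ISR genes gave no call. In the simulations this test recovered 7% of 2-fold and 65% of 4-fold changes at CT15, and 19% and 64% at CT03. An absent call thus does not show that GCN2 leaves the diet response of a gene unchanged. The 3 calls at CT15, Mcm6, Slfn9 and Ugt3a2, became 0 without KO Control replicate 3, KO LeuD replicate 3 or any 1 of the 6 WT libraries, 2 without KO Control replicate 1, and 9 and 19 without KO LeuD replicates 1 and 2. EdgeR on the recovered reads called 1 gene and on all 24 libraries 75, and 1764 genes had an unadjusted p under 0.05. At CT03 limma called 0 genes (1909 at an unadjusted p under 0.05, edgeR on the recovered reads 1, edgeR on all 24 libraries 0). Branched-chain amino acid catabolism there had 19 of 19 negative differences and 10 lower when adjusted over the list alone (9.15e-10, and adjusted p = 0.767 with an estimated correlation). Without KO LeuD CT03 replicate 3 the CT03 difference called 1064 genes, and without KO Control CT03 replicate 1 or 3 it called 1. Of 330 genes called for diet in WT at CT03, 237 (71.8%) had the same sign in KO, against 52.9% of all genes, with a slope of 0.46. Of 28 called at CT15, 19 (67.9%) did, against 54.7%, with a slope of 0.23. These genes were picked by their calls in WT, which alone can bring a slope below 1. Between CT03 and CT15 within WT the slope of the diet effects was 0.55. The slopes thus do not show a weaker diet response in KO.

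The last comparison set KO against WT on the Control diet, where few genes were called. At CT03 Eif3j2 was higher in KO (59.1 ± 5.3 to 557 ± 46.2, 3.22 ± 0.15, adjusted p = 0.000628), as was Tcp11l1 (99 ± 2.95 to 321 ± 39.3, 1.68 ± 0.15, adjusted p = 0.0421). At CT15 Eif3j2 was higher again (64 ± 10.8 to 782 ± 131, 3.59 ± 0.2, adjusted p = 0.0021), and MHC genes differed in both directions. H2-T-ps and H2-T10 were higher in KO by 4.70 ± 0.29 and 3.67 ± 0.27. H2-Q5, H2-Eb1, H2-T23, H2-T22 and H2-Q7 were lower, H2-Eb1 from 1075 ± 225 to 43.9 ± 9.66 (-4.58 ± 0.23, adjusted p = 0.0021). Disp2, a protein of hedgehog release, was lower by -4.38 ± 0.44. Several H2 genes are near-identical paralogs and Eif3j2 has the paralog Eif3j1, so reads can be shared among such genes. No member of the ATF4 and ISR list was called at either time, Ddit3 having -0.72 ± 0.14 at CT03 (adjusted p = 0.433) and Asns 2.13 ± 0.59 at CT15 (adjusted p = 0.791). At CT15, 19 of 19 fatty acid synthesis genes and 12 of 12 Kupffer cell markers were negative with 0 called, and 12 of 12 pancreas acinar markers were positive with 12 higher when adjusted over the list alone. Counts were 2 of 14674 genes at CT03 and 12 of 15031 at CT15 (6 higher, 6 lower), with 1200 and 825 at an unadjusted p under 0.05. Eif3j2 passed without each library at both times, as did H2-Eb1 and H2-T-ps at CT15. At CT03 Tcp11l1 was lost without any 1 of the 6 libraries, with 1 gene called without KO replicate 1, WT replicate 2 or WT replicate 3, 2 without KO replicate 2 or 3 and 3 without WT replicate 1. At CT15 the count was 6 without KO replicate 3, 8 without KO replicate 2, and 3 and 6 without WT replicates 2 and 3. The authors' deposited tables held 95 and 48 genes.

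**Figure D5:**
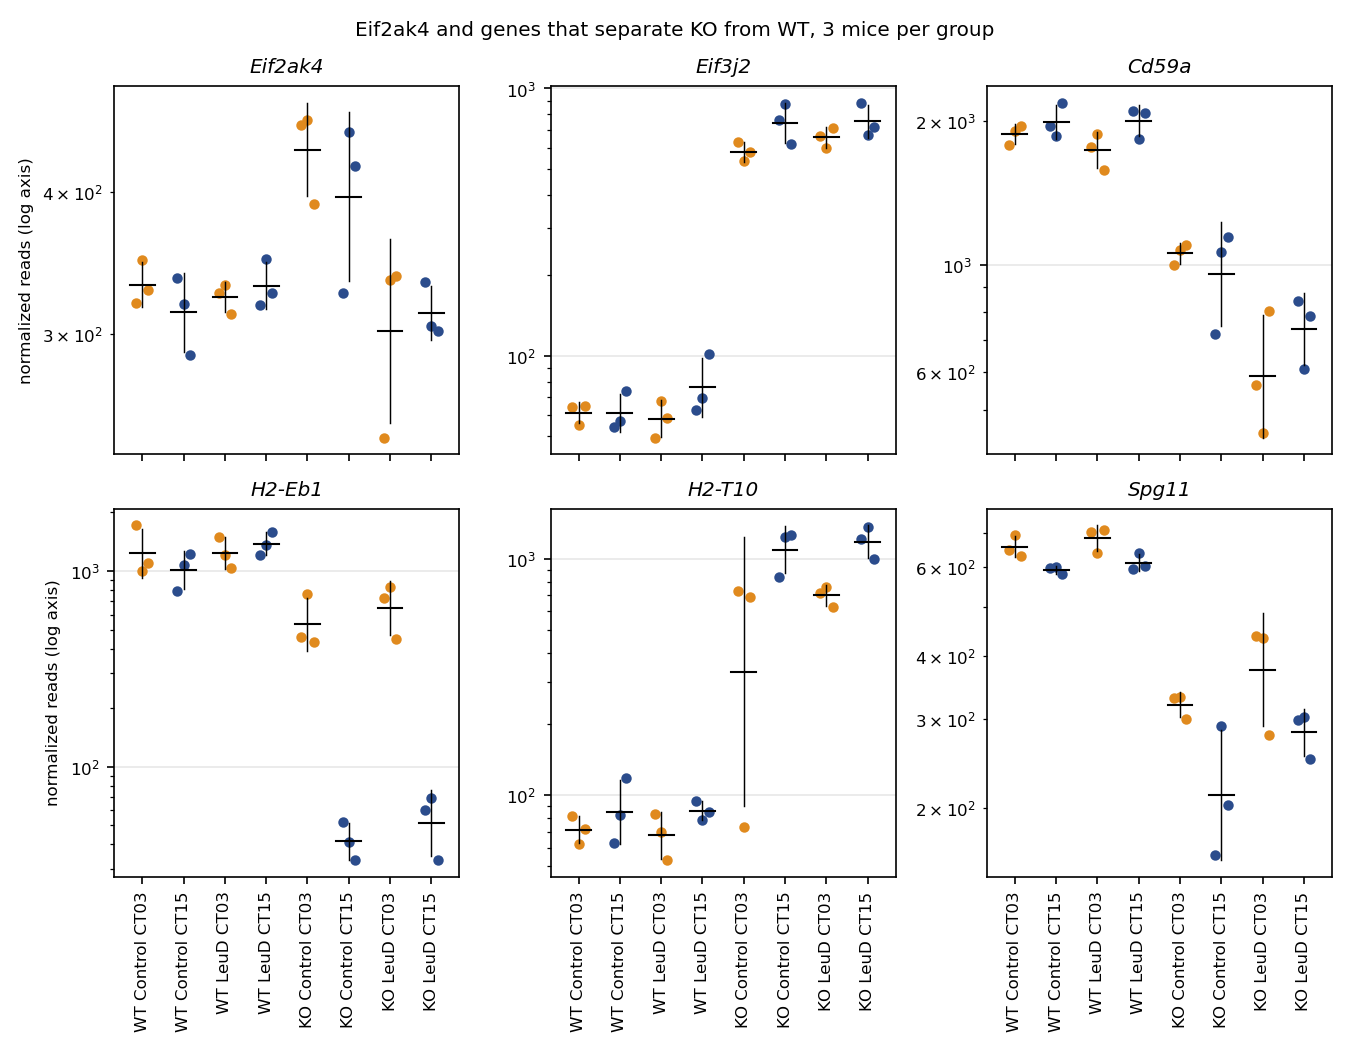
Normalized counts of Eif2ak4, Eif3j2, Cd59a, H2-Eb1, H2-T10 and Spg11 in each library, on a log axis and on 1 scale over 24 libraries, by genotype and diet (points: CT03 orange, CT15 blue; bar: geometric mean; line: 1 SD on the log scale). Eif2ak4 overlaps between genotypes, Eif3j2 lies at 534 to 883 in KO and 49.4 to 101 in WT, and H2-Eb1 lies at 33.2 to 69.2 in KO at CT15 and at 434 or more elsewhere.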

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

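The tests of a difference between a pair of effects were planned before the data were examined; the tests of explanations and the splits in this part were chosen after the results were seen. Each gene in the next 2 paragraphs stood out because its effects in a pair of conditions differed at an adjusted p under 0.05 in the test of the difference. The 3 patterns after them were noticed in the values and came from no such test.

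Between diets, in WT mice, Nfil3 had a time effect of 0.00 ± 0.13 on Control and -1.49 ± 0.12 on LeuD (difference -1.49 ± 0.18, adjusted p = 0.0382). Of 100 splits of the 12 libraries 10 gave at least this 1 gene, and the highest of the others gave 2803. Such counts point to a structure of the samples, since exchanging the labels of 1 table turns the difference of both effects into their sum. The splits of the differences thus hold real effects, and here and below they do not exclude chance but do not speak for it either. In KO mice the difference called 0 genes with limma, with 930 at an unadjusted p under 0.05 and 0 with edgeR on the recovered reads, and all 100 splits gave at least as many (highest 785). Every split reaches a real count of 0, so this share says nothing on chance.

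Between genotypes, on the Control diet, the time effect differed for H2-Eb1 (-0.28 ± 0.23 in WT, -3.67 ± 0.28 in KO, difference -3.38 ± 0.39), H2-T22 (0.16 ± 0.17 and -2.55 ± 0.27, difference -2.71 ± 0.34), H2-Q5 (0.79 ± 0.23 and -3.61 ± 0.48, difference -4.39 ± 0.56) and H2-T23 (-0.07 ± 0.2 and -3.07 ± 0.29, difference -3.00 ± 0.39), each with adjusted p = 0.0264. On the LeuD diet it differed for H2-T22 (-2.49 ± 0.25, adjusted p = 0.00347), H2-Eb1 (-3.78 ± 0.39, adjusted p = 0.00347) and H2-T23 (-2.36 ± 0.26, adjusted p = 0.00441). The 4 genes on Control were reached by 6 of 100 splits (highest other 22) and the 3 on LeuD by 17 of 100 (highest other 2051), which settles nothing on chance for the reason above. H2-Eb1 had 33.2 to 69.2 normalized counts in the 6 KO mice at CT15 and at least 434 in the other 18 mice. At CT15 the diet effect differed between genotypes for Mcm6 (2.85 ± 0.34, adjusted p = 0.0341), Ugt3a2 (-1.22 ± 0.17, adjusted p = 0.0475) and Slfn9 (3.28 ± 0.45, adjusted p = 0.0475). For these 3 genes 4 of 100 splits gave as many (highest other 436), a share under 0.05 for this count alone. As 1 of 6 differences put through this test it does not exclude chance, and 0 genes were called without the acinar libraries or without any 1 of 8 of the 12 libraries (KO Control replicate 3, KO LeuD replicate 3 and all 6 WT libraries). For Mcm6 the difference was 2.63 to 3.09 without each library in turn and 2.66 and 2.85 without the acinar libraries (limits of 200 and 1000 RPM), so its size does not rest on those libraries. These estimates share most of their libraries with the full fit, so they cannot speak for or against chance. At CT03 the difference called 0 genes with limma (1909 at an unadjusted p under 0.05, 1 with edgeR on the recovered reads), and all 100 splits gave at least as many (highest 485), as any split must for a real count of 0.

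The genes that separated KO from WT on the Control diet lay near each other. Of 32 genes shifted the same way in both genotype tables (change over 3 times its SE), 17 lay within 150 measured genes of Eif2ak4, against 0.7 for random places (permutation p = 1e-05, the smallest that 1e+05 permutations can give), so a candidate explanation is DNA of another strain kept around the altered gene. Loss of GCN2 acting regardless of place would put 2.2% of them there, not 53.1%, and is excluded as the whole explanation, while it stays open for the 12 genes outside this region and the H2 region. Among these 12 is Eif3j2 (3.22 ± 0.15 at CT03, 3.59 ± 0.2 at CT15). Its near-identical paralog Eif3j1 lies near Eif2ak4 and was lower in KO (-0.67 ± 0.09 and -0.37 ± 0.12). Reads moved between these paralogs could thus tie Eif3j2 to the region, so its change cannot be assigned to loss of GCN2. For the H2 genes a candidate explanation is another H2 haplotype with an unequal share among KO mice: 6 of 6 KO mice at CT15 had less H2-Eb1 than every other mouse, 5 KO mice at CT03 had H2-T10 above every WT mouse but H2-Eb1 above every KO mouse at CT15, and 1 (KO Control CT03 replicate 2) had H2-T10 of 73.5 and H2-Eb1 of 768. An effect of time on these H2 genes in KO mice cannot be told apart from this, because the share differs with time, and reads shared among paralogs were not tested.

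Pancreas acinar transcripts stood at 3782 to 13365.4 RPM in 3 LeuD libraries. Pancreas tissue in the sample would bring other pancreas genes too: of 18 further pancreas genes measured (20 listed), 16 were higher in those 3 libraries than in each of the 21 others, the exceptions being Prss1 and Bhlha15, which goes with this explanation. Induction by the LeuD diet in most LeuD mice is excluded, since 9 of 12 LeuD libraries held fewer than 100 RPM. Induction in some LeuD mice alone is not excluded by this count, as the pattern was defined by the 3 high LeuD libraries. No other biological explanation was tested.

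KO LeuD CT03 replicate 3 lay away from its mates, as Psat1 stood at 24.3 normalized counts against 626 and 839 and Asns at 409 against 3232 and 2870. On an axis from the KO Control mean (0) to the KO LeuD mean (1) at CT15 it lay at 0.35, its mates at 0.83 and 0.86 and the highest KO Control CT03 library at 0.2, and on an axis of the WT diet effect at CT03 it lay at 0.65 and its mates at 0.79. An exchange of labels with a KO Control CT03 library needs a partner near the mates: on the WT axis KO Control CT03 replicate 3 lay at 0.67 (0.05 and 0.13 in its own mates), which leaves an exchange open, but KO Control CT15 replicate 1 lay at 0.96 there, and the 0.2 and that partner's Gdf15 of 66.1, Psat1 of 33.6, haemoglobin of 276.4 RPM and albumin of 9.47% argue against it. A mouse on the Control diet and a weaker response to LeuD cannot be told apart, since 0.35 lies between both groups and Psat1 and Asns lay at the Control level. Other values lay on the LeuD side: Gdf15 at 982 (mates 2244 and 779, KO Control CT03 66.1 to 224), haemoglobin at 128.6 RPM (at least 212.2 in every Control library) and albumin at 11.81% (at most 10.91% outside KO LeuD). The share of mitochondrially encoded genes lay near the Control side, at 4.14% (mates 2.24% and 2.86%, KO Control CT03 4.28% to 5.13%). It was not the only library apart from its mates. Over all genes KO Control CT15 replicate 1 differed from its mates by a chi-square per degree of freedom of 410.2 and 351.2. For KO LeuD CT03 replicate 3 these values were 251.5 and 203.8. On the WT axis the mates of KO Control CT15 replicate 1 lay at -0.06 and 0.05, far from its 0.96. No explanation was tested for that library.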

How the results depend on the processing

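Thresholds, filters, centring, the block and the removal of each library were planned as alternatives. The pseudocounts, the removal of acinar libraries and the comparison of genotypes on LeuD were chosen after the data were seen. So was the use of both edgeR fits and of the authors' deposited adjusted p as alternatives. The edgeR quasi-likelihood test and the deposited adjusted p had been planned as main tests, for whole counts and for comparisons without library values. The median-ratio normalization and the DESeq2 test, planned for whole counts, and a larger SE, planned for comparisons without library values, were not run. Counts are of genes called, with the value as reported first, and the cause of a move was not tested unless fewer genes or libraries are its construction. For time they are given in the order WT Control (212), WT LeuD (1424), KO Control (6) and KO LeuD (120), and for diet in the order WT CT03 (330), WT CT15 (28), KO CT03 (0 with limma, 2173 at an unadjusted p under 0.05) and KO CT15 (3).

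An adjusted p under 0.01 left 20, 490, 0 and 30 for time, 47, 0, 0 and 0 for diet, and 1 and 6 for genotype on Control at CT03 (2) and CT15 (12). A fold change of at least 2 left 111 and 418 for time in WT, 142 for diet in WT at CT03, and all other counts within 1.5 times. The authors' deposited tables held 907, 2028, 357 and 844 genes for time, 960, 523, 520 and 698 for diet and 95 and 48 for genotype. EdgeR on all 24 libraries called 167, 701, 553 and 1185 for time, 28, 3, 643 and 1213 for diet, 11 and 21 for genotype, 0 and 25 for time by diet in WT (1) and KO (0), 4 and 8 for time by genotype on Control (4) and LeuD (3), and 0 and 75 for diet by genotype at CT03 (0) and CT15 (3). The fit of all 24 libraries pools the spread of WT and KO groups, so its counts can be too high in KO and too low in WT livers. EdgeR on the recovered reads moved diet in WT at CT15 to 14, genotype at CT03 to 1 and diet by genotype to 1 at CT03 and 1 at CT15. A pseudocount of 5 moved genotype at CT03 to 5. For diet by genotype an adjusted p under 0.10 gave 2 and 94, and a mean normalized count of at least 100 gave 1 and 15. Without the acinar libraries (limits of 1000 and 200 RPM) time in KO LeuD went to 9 and 9, diet in WT at CT15 to 12 and 12, diet in KO at CT15 to 0 and 87, time in KO Control to 76 (limit of 200), time by diet in WT to 0 and 0, time by genotype on LeuD to 0 and 0 and diet by genotype at CT15 to 0 and 0.

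Leaving out 1 library at a time (a lone pair is then set against 3, with pooled spread) gave 4 to 133, 561 to 1176, 0 to 5 and 31 to 605 for time, 75 to 443, 0 to 132, 0 to 1234 and 0 to 203 for diet, and 1 to 3 and 3 to 9 for genotype. Differences gave 0 to 7 (time by diet, WT), 0 to 1 (KO), 0 to 4 (time by genotype, Control), 3 to 36 (LeuD), 0 to 1064 (diet by genotype, CT03) and 0 to 19 (CT15). Of the 210 list tests 137 passed with a correlation preset at 0.05, 214 with ranks and 0 with an estimated correlation.

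Replicate numbers did not pair the mice: libraries of the same number in different groups had deviations with a median correlation of 0.04 over 84 pairs (-0.38 to 0.38, 24 of them over 0.1), against -0.03 over 168 other pairs, and 10 of 24 libraries correlated best with their own number. With the number as a block the counts were 42, 747, 0 and 69 for time, 304, 64, 0 and 0 for diet, 1 and 12 for genotype, and 1, 0, 1, 3, 0 and 0 for the differences in the order above. The 1 gene of time by diet in WT was then another gene, as the Nfil3 call was lost (0 shared), and 7 of the 12 for genotype at CT15 were shared. For KO versus WT on LeuD edgeR on all 24 libraries called 135 at CT03 (6) and 543 at CT15 (273), removal of acinar libraries left 4 and 24, and removal of each library gave 3 to 1939 and 31 to 357. Over genes named by the rule and called, 901 of the planned changes of setting kept the call and 270 lost it, and with settings added later 1167 kept and 256 lost it. Removal of 1 library kept 817 and lost 641, and 0 turned direction. In the simulated tables of KO libraries alone 9% to 19% of 2-fold changes were recovered, so a low count there does not show that few genes differed.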

Other observations

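The comparison of KO with WT on the LeuD diet, in none of the deposited tables, was added after the data were examined, as were the interferon list and the splits in this part, while the gene calls of the other comparisons were planned. At CT15 KO livers had more Asns (675 ± 158 in WT, 2160 ± 484 in KO, 1.68 ± 0.21, adjusted p = 0.0139) and less Trib3, a pseudokinase induced in the stress response (327 ± 60.3 and 138 ± 2.25, -1.22 ± 0.18, adjusted p = 0.0201). On the Control diet at CT15 Asns averaged 161 ± 29.5 in WT and 916 ± 783 in KO and was not called. The higher level in KO is thus not shown to be particular to LeuD. On LeuD at CT15 Mcm6 was higher in KO (207 ± 6.54 and 810 ± 253, 1.92 ± 0.22, adjusted p = 0.011), and 4 of 16 cell cycle genes were called higher, 16 were positive and 10 passed when adjusted over the list alone (camera adjusted p = 1.37e-09, adjusted p = 0.429 with an estimated correlation). Of the major urinary protein genes, which are near-identical, Mup1 was lower (254 ± 113 and 14.6 ± 7.81, -4.03 ± 0.45, adjusted p = 0.00912) and Mup11 too (-4.63 ± 0.84), while the more abundant Mup20 averaged 35530 ± 23000 in WT and 28760 ± 19600 in KO. At CT03 Nudt7, a peroxisomal coenzyme A diphosphatase, was lower (11410 ± 1070 and 3435 ± 294, -1.73 ± 0.12, adjusted p = 0.00416), and Eif3j2, H2-T-ps, H2-T10 and Cib3 were higher. Of these 5 genes, Nudt7 and Cib3 lost their call on removal of at least 1 library, while the other 3 passed without each library in turn. In total 6 genes were called at CT03 (5 higher, 1 lower) and 273 at CT15 (179 higher, 94 lower) of 14420. At CT03 the count was 1939 without KO replicate 3 and 3 without WT replicate 3, and at CT15 it was 60 without KO replicate 3 and 71, 31 and 75 without WT replicates 1, 2 and 3. Genes of this comparison were named outside the rule: the largest changes each way, a set of clock, stress and cell cycle genes, and the called members of the interferon list. Of the 48 named genes called at CT15, 29 came from that list, picked because they were called, and none of those passed without each library in turn. In all 10 of the 48 did pass, Asns and Mup1 among them but not Mcm6, Trib3 or Mup11. The rest of the 10 were Eif3j2, H2-Eb1, H2-K2, H2-Q2, H2-Q5, H2-T-ps, H2-T10 and H2-T22. H2-T-ps had a change of 5.67 ± 0.22 and H2-Eb1 of -4.71 ± 0.27 at CT15. For H2 genes another haplotype is a candidate explanation, as given above.

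Interferon-stimulated genes, a list written after the values were seen, had 29 of 50 members called higher in KO than in WT on LeuD at CT15, and 50 positive (median 1.37). Since the list was chosen for this pattern, these counts describe it and do not test it. Usp18, which restrains interferon signalling, went from 253 ± 9.6 to 1801 ± 1210 (2.63 ± 0.37, adjusted p = 0.019), and Irf9, a subunit of the interferon-activated factor, was higher by 1.41 ± 0.16. The count of 29 was 17 and 16 without KO replicates 1 and 3, 5, 0 and 13 without WT replicates 1, 2 and 3, and 0 without the 2 acinar libraries (limma). The median was 1.30 without WT replicate 2 and 1.43 without the acinar libraries, while the whole comparison called 31 and 24 genes. Without each library in turn 48 to 50 members were positive. At CT03 the same comparison had 42 of 50 positive (median 0.34) with 0 called by limma, and 22 called (median 0.59) without KO replicate 3. Relative to WT LeuD at CT15 (-0.13 to 0.23), the list mean of a library was 0.99 to 1.97 in KO LeuD, -0.51 to 0.13 in KO Control and 0.36 to 0.55 in WT Control at CT15. At CT03 it was 0.21 to 1.26 in KO LeuD, 0.61 to 0.92 in KO Control, 0.49 to 1.03 in WT Control and 0.18 to 0.35 in WT LeuD. Lymphocyte markers had 10 of 10 negative (median -1.01) with 0 called by limma. On the Control diet at CT15, 1 of 49 measured members was positive (median -0.53) with 0 called by limma. In KO livers LeuD against Control at CT15 gave 49 of 50 positive (median 1.48) with 0 called by limma, and in WT livers 3 of 50 (median -0.38), while the difference of these diet effects had 49 of 50 positive (median 1.83) with 0 called.

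Other splits of the 6 libraries of a table were counted for each comparison of a pair of groups. With 3 against 3 there are 10 splits, the real one included, too few for a share under 0.05. For time 1 of 10 gave a count as high as the real one in each condition: WT Control 212 (highest other 0), WT LeuD 1424 (0), KO Control 6 (0) and KO LeuD 120 (3). For diet 1 of 10 did so in WT at CT03 (330, highest other 1) and at CT15 (28, highest other 1), 10 of 10 in KO at CT03 (0, highest other 1) and 2 of 10 in KO at CT15 (3, highest other 3). The 10 of 10 follows from the real count of 0 and says nothing on chance. For genotype 1 of 10 did so on Control at CT03 (2, highest other 0) and CT15 (12, highest other 0) and on LeuD at CT03 (6, highest other 0) and CT15 (273, highest other 3). For the list tests 6 of 40 sets of labels, the real set included, gave at least the real 210 (highest other 225), so chance is not excluded for that count.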
